A study of Homo sapiens with 8 samples.

How the data were processed

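RNA was sequenced from 8 PANC-1 libraries, 4 transfected with a scrambled siRNA and 4 with a BARD1 siRNA for 48 h. Per the labels' protocols, total RNA was column-purified, messenger RNA was captured on poly-T beads and fragmented, and first-strand cDNA was primed with random hexamers. The labels describe both a strand-specific and a non-specific second-strand step without saying which was used, so strandedness is not stated, and genes that overlap an antisense neighbour are less certain. Poly-T capture and random priming leave little signal from transcripts without a poly-A tail.

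The authors deposited a table of whole-number read counts per gene and a table of FPKM values per gene, each with 1 column per library. Per the submitters' processing notes, reads were handled with fastp, HISAT2 (2.0.5) and featureCounts; the settings are not given in the sources used here. Those notes name the builds GRCh37 and hg19, but the coordinates in the deposited tables are those of GRCh38: all 58735 gene identifiers, with identical starts and ends, are in GENCODE release 29 on that build. All coordinates here are GRCh38, as the tables give them, and which build the reads were aligned to is not settled. featureCounts leaves out reads that fall on exons of more than 1 gene unless told otherwise. Of 99 named genes, 3 share over 20% of their exonic bases with another gene on the same strand and 4 with one on the opposite strand. In each library, every deposited FPKM value equalled the count divided by gene length and total count, times 1 constant per library between 0.97 and 1.03.

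Libraries were grouped by their labels. Pairs of libraries within a group differed by more than sampling noise (chi-square per gene 4.30 to 18.0), so no library was counted as a duplicate. Symbols shared by several genes (1741 entries) were kept apart by identifier.

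The main test was edgeR (4.0.16, R 4.3.3) on the deposited counts: filterByExpr with its defaults, TMM scaling, a robust quasi-likelihood fit of siBARD1 against siSCR without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. 15287 genes passed the filter. Standard errors were the log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled totals. Gene lists were tested with camera in limma (3.58.1) at a preset inter-gene correlation of 0.01, adjusted over 22 lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes, and fry asks whether a list's genes move, on balance, one way. Single values of 4 against 4 libraries were compared by exact two-sided permutation over 70 assignments, for which 0.0286 is the smallest p. Levels of each list per library, the mean log2 CPM of its members, were added after seeing the data.

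The 22 gene lists, the 4 marker lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named BARD1 and BRCA1; then the 10 protein-coding genes with the largest positive and the 10 with the largest negative log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups; and in each list the 2 largest changes in each direction among members that passed, or the member with the smallest p where none passed. 1 of the 22 lists and some named genes are not reported here.

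Sequences were searched in 1 transcript per protein-coding gene from GENCODE 29, the one with the longest annotated 3′ UTR. That transcript need not be the form expressed in these cells. Residuals of log2 fold change were taken from a fit on 3′ UTR length, 3′ UTR GC content and coding length. For each of 16384 7-base sequences, the mean residual of genes with the sequence in the 3′ UTR was compared with that of other genes. The search used a random 6330 of 12660 genes, and the sequence found was then tested on the other 6330 against 1000 shuffles. Only 3′ UTRs of at least 20 bases were searched.

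Alternatives were RLE, upper-quartile and total-count scaling; no low-count filter and a minimum of 1 CPM in 4 libraries; protein-coding genes only; DESeq2 (1.42.0); limma-voom; limma on log2(FPKM + 1) and log2(FPKM + 0.1); the replicate number as a block; leaving out each library; an adjusted p under 0.01; and a test against a fold of 1.2. An alternative over transcripts without the sequence CTACCAG was added after seeing the data.

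The edgeR step was tested on counts simulated for 15287 genes with the means and totals of the siBARD1 and siSCR libraries, 200 of them changed. It called 36% of genes changed 1.25-fold, 66% at 1.5-fold, 86% at 2-fold and 100% at 4-fold, with 7 false calls among 151. Totals were 17816547 to 28590710 counts per library. Many 1.25-fold changes in single genes were missed in this simulation. Far fewer genes were changed in it (200) than were called in the data (5946), which makes the adjusted threshold stricter in the simulation. The recovered shares are therefore not the sensitivity in the data. A list lowered in simulated data was called and 0 of 20 unchanged lists were, and a planted 7-base sequence was found. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for the sequence search and the figures.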

Results

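The series profiled polyadenylated RNA from PANC-1, an established human pancreatic ductal adenocarcinoma cell line, 48 h after transfection with small interfering RNA (siRNA). The design asked which transcripts differ when BARD1 is silenced. BARD1 is the RING-domain partner of BRCA1 in a ubiquitin ligase that acts in homologous recombination repair. 4 libraries came from cells given a scrambled control siRNA (siSCR) and 4 from cells given a BARD1 siRNA (siBARD1), with replicates numbered 1, 3, 4 and 5 in both groups. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

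Total counts assigned to genes were 24367315, 17816547, 21797561 and 20395146 in siSCR replicates 1, 3, 4 and 5, and 20185800, 25510502, 28590710 and 21816955 in siBARD1 replicates 1, 3, 4 and 5. The group totals did not differ in an exact two-sided permutation test (p = 0.286, smallest possible p 0.0286). Genes with at least 1 count numbered 22604 ± 443 (SD, n = 4) in siSCR and 23334 ± 356 (SD, n = 4) in siBARD1. Ribosomal protein genes took 4.61% ± 0.33 of counts in siSCR and 3.99% ± 0.12 in siBARD1, and the 20 most abundant genes took 7.72% ± 0.22 and 7.22% ± 0.18 (SD, n = 4 each). These 3 measures separated the groups without overlap, each with an exact permutation p of 0.0286 and an adjusted p of 0.0571 over 6 measures. Mitochondrially encoded transcripts took 2.17% ± 0.57 and 2.80% ± 0.30 of counts (exact permutation p = 0.114, adjusted p = 0.171), with the lowest share, 1.38%, in siSCR replicate 1. The protein-coding share was 98.3% in both groups (exact permutation p = 0.771). The first principal component of log2 CPM (counts scaled to a common library total) held 46.1% of the variance and separated the groups. The second component held 15.5% and set siSCR replicate 1, at 31.5, apart from the other 7 libraries, which lay between -12.5 and 5.59.

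BARD1 (ENSG00000138376; chromosome 2, 214725646 to 214809711, minus strand, GRCh38) was measured first as the siRNA target. Its counts were 415, 382, 381 and 424 in siSCR replicates 1, 3, 4 and 5 and 67, 75, 97 and 55 in the matching siBARD1 libraries. BARD1 stood at 19.5 ± 2.33 CPM in siSCR and 3.0 ± 0.40 CPM in siBARD1 (SD, n = 4 each), so that 15.4% of the transcript remained (95% confidence interval 13.0% to 18.3%). The log2 fold change was -2.69 (SE 0.12, edgeR quasi-likelihood adjusted p = 7.41e-11). All 4 siBARD1 values lay below all 4 siSCR values (exact permutation p = 0.0286, the smallest possible). The authors' FPKM values for BARD1 were 3.20 ± 0.38 and 0.490 ± 0.066 (SD, n = 4 each). BRCA1 (ENSG00000012048; chromosome 17, 43044295 to 43170245, minus strand), the binding partner of BARD1, stood at 31.1 ± 1.87 CPM in siSCR and 24.6 ± 2.91 CPM in siBARD1. Its log2 fold change was -0.33 (SE 0.08, adjusted p = 0.0042), and its transcript carried 3 copies of the sequence CTACCAG, described with the steepest falls, outside the 3′ UTR.

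**Figure D1:**
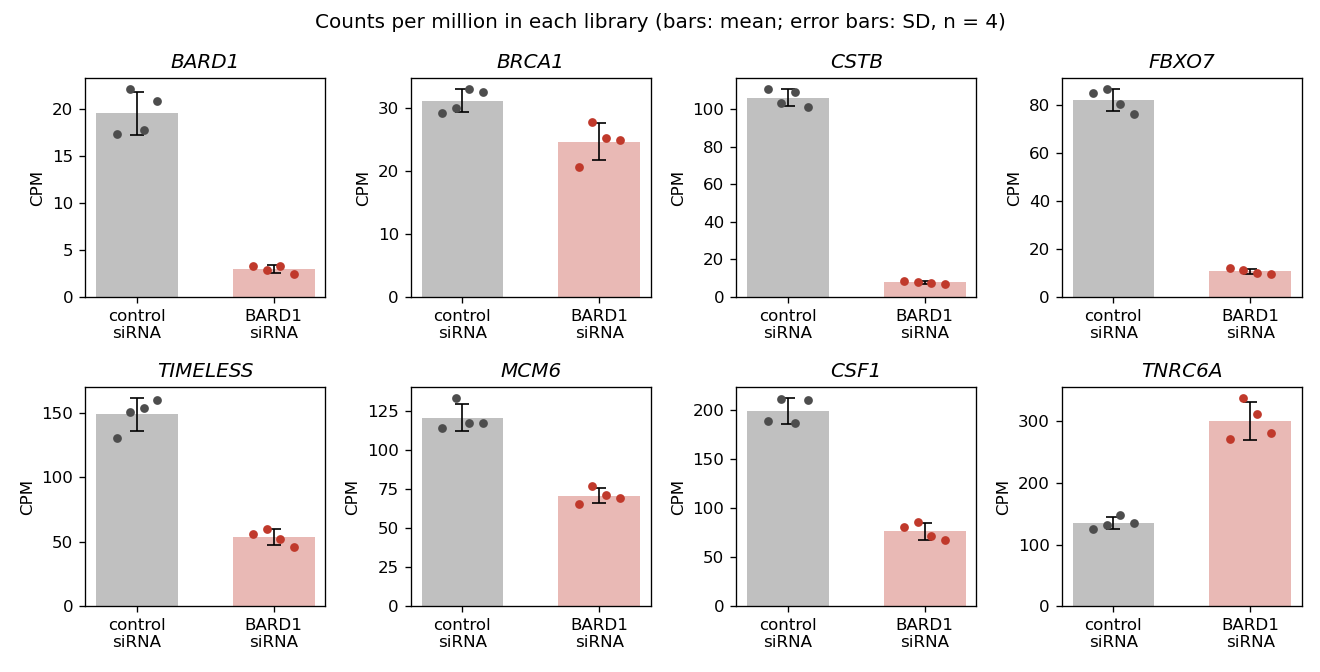
CPM of 8 named genes in each library of cells given control siRNA or BARD1 siRNA. Bars show the mean of 4 libraries, error bars the SD and points the single libraries; BARD1 fell from a mean of 19.5 to 3.0 CPM, CSTB from 106.0 to 7.81 CPM, and TNRC6A rose from 135.0 to 300.2 CPM.

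Of 15287 genes tested, 5946 changed at an edgeR adjusted p under 0.05, with 2889 higher and 3057 lower in siBARD1. Changes were mostly small: the median size among changed genes was 0.36 on the log2 scale, and 320 genes changed at least 2-fold, 141 higher and 179 lower. The 4 libraries of one group all lay above the 4 of the other for 5522 genes, or 36.1% of those tested, against 2.86% by chance. With scaling by total count only, 3616 genes were higher and 2478 lower, so the balance of directions depended on the scaling. The count of 2-fold changes was 84 with limma on log2(FPKM + 1) and 200 on log2(FPKM + 0.1), scales that shrink the changes of low genes.

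**Figure D2:**
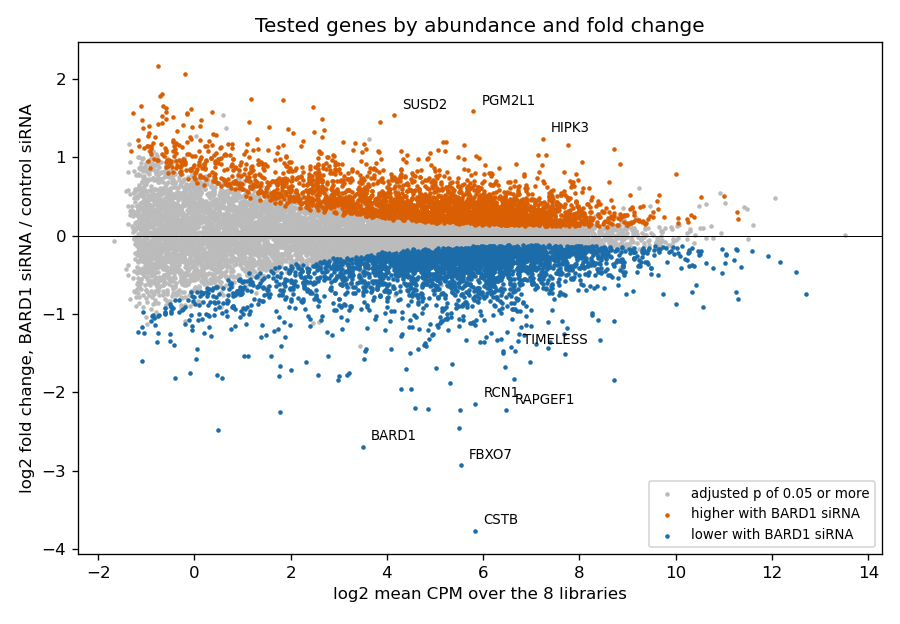
Log2 fold change of BARD1 siRNA over control siRNA against log2 mean CPM over the 8 libraries for the 15287 genes tested. Coloured points are the 2889 genes higher and 3057 genes lower at an adjusted p under 0.05; CSTB, at -3.76, and FBXO7, at -2.93, fell further than BARD1, at -2.69.

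The steepest falls among protein-coding genes at 5 CPM or more were in genes of varied function, and BARD1 ranked 30 by p-value. CSTB, which encodes cystatin B, an inhibitor of lysosomal cysteine proteases, fell 13.6-fold, from 106.0 ± 4.68 to 7.81 ± 0.67 CPM (SD, n = 4 each; log2 fold change -3.76, SE 0.07, adjusted p = 9.35e-16). FBXO7, an F-box protein of ubiquitin ligase complexes, fell 7.62-fold, from 82.0 ± 4.65 to 10.8 ± 1.0 CPM (log2 fold change -2.93, SE 0.07). ACP7 (-2.46, SE 0.08), RAPGEF1, an exchange factor for the small GTPase RAP1 (-2.23, SE 0.06), and SLC44A1, a choline transporter (-2.23, SE 0.13), also fell. TMEM120A had a log2 fold change of -2.21 (SE 0.08) and PM20D2 of -2.20 (SE 0.07). RCN1, a calcium-binding protein of the secretory pathway, had -2.14 (SE 0.06) and KLHL23 had -1.96 (SE 0.08). The adjusted p of these 9 genes ranged up to 4.81e-07, the value for SLC44A1. About 20% of the exonic bases of RCN1 are shared with another annotated gene on the same strand, so its counts are less certain.

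The transcripts of all 10 genes with the steepest falls, BARD1 included, carried the 7-base sequence CTACCAG, compared with 2 of the 10 genes with the steepest rises and 24.2% of the 12722 protein-coding transcripts searched. These genes were not limited to those left out of the search for the sequence. Positions are those in the annotated transcript with the longest 3′ UTR, which may not be the form expressed. CSTB had 3 copies, all in the 3′ UTR, SLC44A1 had 4, of which 2 lay there, and BARD1 had 2, of which 1 lay there. RAPGEF1 had 4 copies, none of them in the 3′ UTR. FBXO7, ACP7 and TMEM120A also carried the sequence only outside the 3′ UTR. Over all searched genes, including those used to find the sequence, 69 of the 144 that fell at least 2-fold (47.9%) carried it in the 3′ UTR, compared with 7.68% of the other 12516 genes. Genes with no copy in the 3′ UTR had a median log2 fold change of 0.01, those with 1 copy -0.11 and those with 2 or more copies -0.13. Falls of at least 2-fold were seen in 75 of 11630 genes with no copy, 61 of 920 with 1 and 8 of 110 with 2 or more. Among the 920 with 1 copy, 358 were lower and 163 higher at an adjusted p under 0.05 in edgeR. Among 9638 tested protein-coding genes whose transcripts lacked the sequence, a subset chosen after seeing the data, 3909 changed, 2125 higher and 1784 lower, and 111 changed at least 2-fold. Over all 12751 protein-coding genes tested, 5542 changed, so the share that changed was similar without the sequence.

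The steepest rises among protein-coding genes at 5 CPM or more were smaller than the steepest falls. PLSCR4, a member of the phospholipid scramblase family, rose 3.10-fold, from 2.65 ± 0.81 to 8.36 ± 1.54 CPM (SD, n = 4 each; log2 fold change 1.63, SE 0.19, adjusted p = 5.85e-06). PGM2L1, which makes glucose bisphosphate, rose 2.99-fold, from 27.6 ± 5.70 to 83.1 ± 12.4 CPM (log2 fold change 1.58, SE 0.16), and the surface protein SUSD2 rose 2.90-fold (1.53, SE 0.10). TPPP3, a tubulin-binding protein (1.48, SE 0.19), ANKRD46 (1.45, SE 0.10), RAB11FIP4, an effector of RAB11 (1.35, SE 0.16), and CPEB3, an RNA-binding regulator of translation (1.32, SE 0.15), also rose. ACVR2B, an activin receptor, rose 2.38-fold (SE of the log2 fold change 0.14). TFPI, the inhibitor of the tissue factor coagulation pathway, rose 2.29-fold (SE of the log2 fold change 0.12). HIPK3, a nuclear kinase, had the smallest adjusted p of the 10, 1.71e-11, and went from 90.0 ± 4.58 to 212.1 ± 7.72 CPM (1.24, SE 0.05). The largest adjusted p of the 10 was 6.14e-05, for PGM2L1.

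Genes of the G1/S transition and DNA replication fell together. Of 47 members, 40 fell, 0 rose and 7 did not pass in edgeR, and adjusted over the list alone 41 fell and 0 rose. At an unadjusted p under 0.05, 41 were lower and 0 higher, and DESeq2, limma-voom and limma on FPKM each called 40 lower and 0 higher; without siBARD1 replicate 1, 1 rose. The median log2 fold change was -0.48. MCM6, a subunit of the replicative helicase, fell from 120.7 ± 8.69 to 70.8 ± 4.95 CPM (SD, n = 4 each; -0.77, SE 0.06, adjusted p = 5.98e-08), and E2F2, a transcription factor that drives S-phase entry, had -0.70 (SE 0.11, adjusted p = 1.15e-04). The MCM6 transcript carried CTACCAG once and that of E2F2 did not. The list passed the camera test against the other genes (adjusted p = 4.58e-15 at a preset inter-gene correlation of 0.01), but not when the correlation was estimated from the libraries (adjusted p = 0.508). The mean level of the list lay lower in all 4 siBARD1 libraries than in all 4 siSCR libraries, by 0.44 on average on the log2 scale (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0898 over 22 lists).

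Homologous recombination is the pathway in which BARD1 acts. Of 32 members of this list tested, 17 fell, 3 rose and 12 did not pass; adjusted over the list alone, 18 fell and 3 rose, and the median log2 fold change was -0.21. Only 1 rose without siSCR replicates 4 or 5 or siBARD1 replicate 1. RAD51C, which acts in strand exchange during repair, fell from 14.0 ± 0.82 to 9.21 ± 1.03 CPM (SD, n = 4 each; -0.60, SE 0.10, adjusted p = 1.53e-04), and XRCC2, a member of the same family of repair proteins, had -0.52 (SE 0.14, adjusted p = 0.0085) with overlapping libraries. RAD50, of the MRE11 complex that senses broken ends, had 0.39 (SE 0.09), but 79.7% of its exonic bases are shared with another annotated gene. The camera adjusted p was 0.0358, and it was 0.837 with an estimated correlation. The call did not hold without siSCR replicate 4 (adjusted p = 0.0581), siSCR replicate 5 (0.0554) or siBARD1 replicate 1 (0.103), with scaling by total count only (0.0531), with a minimum of 1 CPM (0.0622) or among protein-coding genes (0.0698).

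None of the other DNA repair lists passed the camera test, and most had members that moved each way. Of 23 Fanconi anaemia and crosslink repair genes, 7 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.410). The number that fell ranged from 3 without siSCR replicate 5 to 11 without siSCR replicate 1, and 5 rose without siBARD1 replicate 3. UBE2T, the ubiquitin-conjugating enzyme that acts on FANCD2, fell 2.31-fold, from 40.5 ± 4.0 to 17.5 ± 0.72 CPM (SD, n = 4 each; -1.21, SE 0.08), and FANCE had -0.66 (SE 0.10). REV3L, the catalytic subunit of translesion polymerase zeta, rose from 104.4 ± 6.43 to 194.9 ± 15.8 CPM (0.90, SE 0.06). In the checkpoint signalling list of 23 genes, 8 fell and 7 rose (9 and 7 adjusted over the list alone; camera adjusted p = 0.376). The number that fell was 5 without siSCR replicate 4 or siBARD1 replicate 5 and 10 without siSCR replicate 1. TIMELESS, a fork protection protein, fell 2.77-fold, from 148.9 ± 12.8 to 53.7 ± 5.95 CPM (-1.47, SE 0.08), and TOPBP1, an activator of ATR, had -0.65 (SE 0.06). The kinase ATM had 0.41 (SE 0.07). The UBE2T, TIMELESS, TOPBP1 and REV3L transcripts carried CTACCAG outside the 3′ UTR, and those of FANCE and ATM lacked it.

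In the list of PARP and base excision repair genes, 10 of 23 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.260). UNG, a uracil glycosylase that is also in the replication list, had a log2 fold change of -0.54 (SE 0.06). PARP3 had 0.36 (SE 0.07), with 2 copies of CTACCAG outside the 3′ UTR. Among 18 end joining genes 4 fell and 0 rose in edgeR (4 and 0 adjusted over the list alone, in DESeq2 and in limma; 6 and 1 at an unadjusted p under 0.05; camera adjusted p = 0.580), among them SHLD2 of the shieldin complex (-0.33, SE 0.06), with CTACCAG in the 3′ UTR. In this list 1 rose without siSCR replicates 1 or 4 and 2 without siBARD1 replicate 5. Of 25 nucleotide excision repair genes, 7 fell and 6 rose (7 and 6 adjusted over the list alone; camera adjusted p = 0.686), including the damage sensor DDB2 (-0.48, SE 0.07) and the coupling factor ERCC6 (0.46, SE 0.06). Of 20 genes tied to PARP inhibitor and platinum response, 6 fell and 3 rose (6 and 3 adjusted over the list alone; camera adjusted p = 0.686). The drug efflux transporter ABCC1, whose transcript carried 3 copies of CTACCAG, had -0.47 (SE 0.07), and the copper transporter ATP7A had 0.55 (SE 0.08).

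Of 46 genes of G2/M and mitosis, 23 fell, 5 rose and 18 did not pass (26 and 5 adjusted over the list alone), with a median log2 fold change of -0.16; 3 rose without siBARD1 replicate 4. CENPI, a centromere protein, fell from 42.4 ± 4.18 to 24.6 ± 2.29 CPM (SD, n = 4 each; -0.78, SE 0.08), and the mitotic kinase AURKA had -0.51 (SE 0.06); both transcripts carried CTACCAG once. HMMR, a spindle-associated protein, had 0.42 (SE 0.06) and the kinetochore protein CENPF had 0.26 (SE 0.06). The camera adjusted p was 0.0256, and it was 0.837 with an estimated correlation. The call did not hold without siSCR replicate 5 (adjusted p = 0.0554) or siBARD1 replicate 1 (0.160), with scaling by total count only (0.0531), with a minimum of 1 CPM (0.0508), among protein-coding genes (0.0583), among transcripts without CTACCAG (0.0682) or in the fry test (0.0833).

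The list of NF-kB signalling and inflammatory secretion also passed the camera test only at the preset correlation. Of 18 members tested, 8 fell, 1 rose and 9 did not pass (9 and 1 adjusted over the list alone), with a median log2 fold change of -0.19; 0 rose without any 1 library other than siSCR replicate 5. CCL2, a monocyte chemokine, fell 2.97-fold, from 17.3 ± 1.41 to 5.84 ± 1.5 CPM (SD, n = 4 each; -1.57, SE 0.15, adjusted p = 1.27e-06). CSF1, a macrophage growth factor, fell 2.61-fold, from 199.4 ± 13.3 to 76.3 ± 8.55 CPM (-1.39, SE 0.07, adjusted p = 2.48e-09). Neither transcript carried CTACCAG. The camera adjusted p was 0.00111, and it was 0.498 with an estimated correlation. Of 21 immediate early genes, 9 fell and 1 rose (9 and 2 adjusted over the list alone), with a median of -0.31; 0 to 2 rose without single libraries. EGR1, a serum-induced transcription factor, stood at 4.46 ± 1.08 and 1.54 ± 0.18 CPM (-1.54, SE 0.20, adjusted p = 1.13e-05; CTACCAG once, outside the 3′ UTR), and FOSL1, an AP-1 subunit, had -0.75 (SE 0.12). The camera adjusted p of the immediate early list was 0.0245, but 0.747 with an estimated correlation and 0.107 among transcripts without CTACCAG.

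The list of small RNA silencing machinery passed the camera test only at the preset correlation. Of 14 members tested, 7 rose, 1 fell and 6 did not pass (7 and 1 adjusted over the list alone), with a median log2 fold change of 0.21; 2 fell without siSCR replicate 1. TNRC6A, a scaffold of the microRNA-guided silencing complex, rose 2.22-fold, from 135.0 ± 9.61 to 300.2 ± 30.5 CPM (SD, n = 4 each; 1.15, SE 0.07, adjusted p = 8.53e-09). AGO4, an Argonaute protein, stood at 27.5 ± 7.05 and 48.6 ± 8.51 CPM (0.81, SE 0.19, adjusted p = 0.0111), although its 3′ UTR carried CTACCAG once. EIF2AK2, the kinase PKR that senses double-stranded RNA, had -0.23 (SE 0.05). The camera adjusted p was 0.00262, but 0.508 with an estimated correlation and 0.115 among transcripts without CTACCAG. That last set leaves out AGO4, which rose, so the lost call does not show that the rise depends on the sequence.

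**Figure D3:**
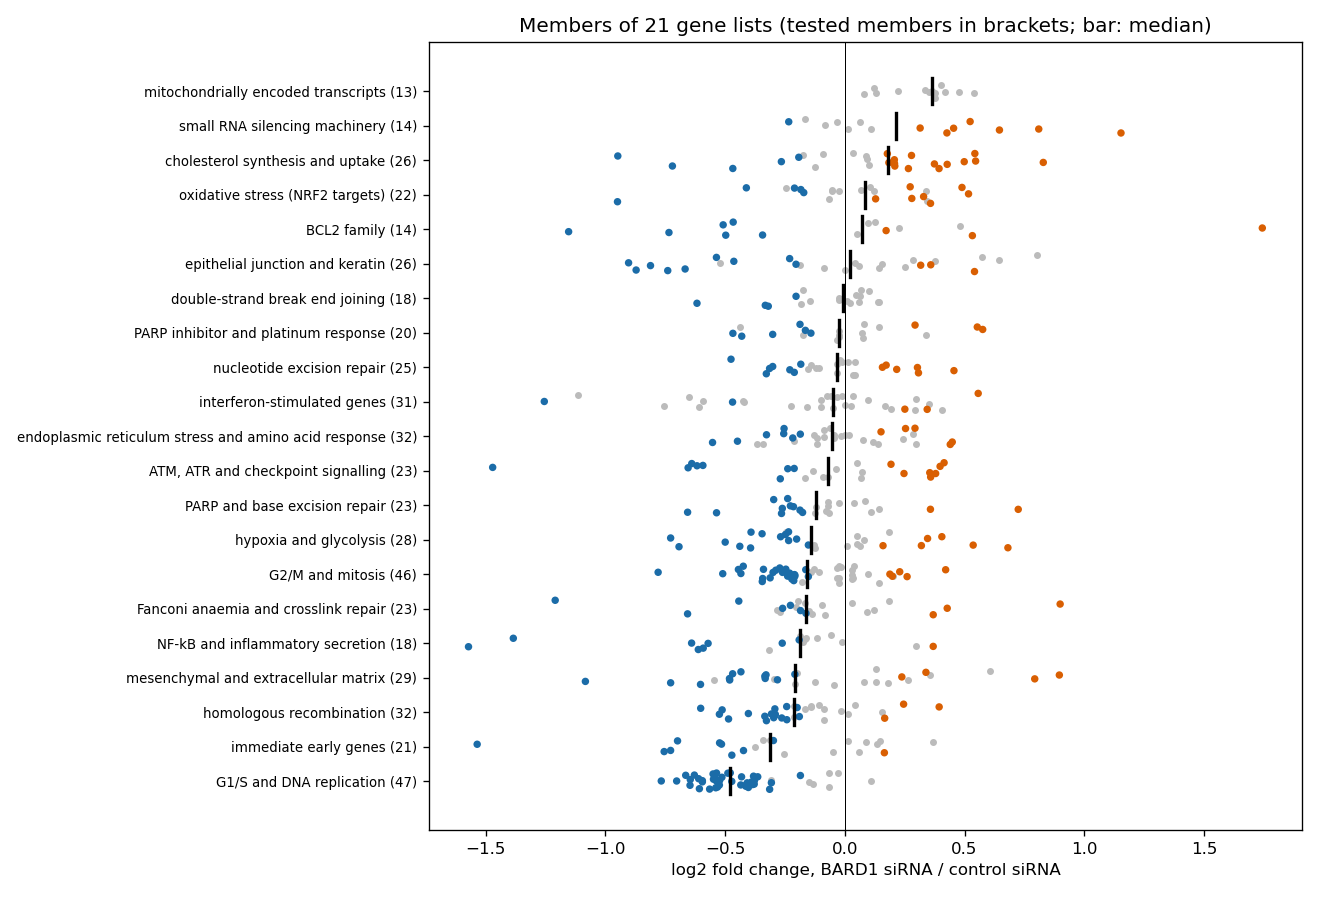
Log2 fold change of BARD1 siRNA over control siRNA for every tested member of 21 gene lists, with list names on the vertical axis. Orange and blue points rose or fell at an adjusted p under 0.05, grey points did not pass, and black bars are medians; the G1/S and DNA replication list has the lowest median, -0.48.

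Stress and signalling lists showed changes in single genes without a list call. Of 31 interferon-stimulated genes, 3 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.686). Without siSCR replicate 1, 5 rose and 2 fell and the median turned from -0.05 to 0.14, and without siSCR replicates 3 or 5 only 1 rose. Mean levels of this list spread from -0.34 to 0.51 on the log2 scale among the siSCR libraries, with replicate 1 the highest. The antiviral oligoadenylate synthetase OAS3 fell from 43.6 ± 4.51 to 18.3 ± 1.76 CPM (SD, n = 4 each; -1.26, SE 0.09), with CTACCAG in the 3′ UTR, and IFIT5 had -0.47 (SE 0.08) without it. Of 32 genes of endoplasmic reticulum stress and the amino acid response, 5 rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.638), with the cystine transporter SLC7A11 at 0.44 (SE 0.08) and CTACCAG once in its transcript. Only 3 of this list rose without siSCR replicate 3 or siBARD1 replicate 5. Of 22 NRF2 targets, 7 rose and 5 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.608), but only 2 fell without siBARD1 replicates 1 or 5 and 3 without siSCR replicate 3. The thioredoxin reductase TXNRD1 had 0.52 (SE 0.11), and UGDH, whose transcript carried CTACCAG once, had -0.95 (SE 0.09).

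In metabolism, 14 of 26 genes of cholesterol synthesis and uptake rose and 5 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.148). STARD4, a sterol transporter, stood at 10.9 ± 1.96 and 19.4 ± 0.71 CPM (SD, n = 4 each; 0.83, SE 0.11), and MSMO1, a sterol oxidase, had 0.55 (SE 0.09). INSIG1, which retains the sterol sensor complex, had -0.95 (SE 0.10) and the desaturase gene SCD had -0.72 (SE 0.16), both with CTACCAG in the 3′ UTR. The cholesterol list passed camera without siSCR replicate 1 (adjusted p = 0.0147), among transcripts without CTACCAG (0.00169) and with no low-count filter (0.0356), all at the preset correlation; over all genes its adjusted p was 0.837 with an estimated correlation. Of 28 hypoxia and glycolysis genes, 13 fell and 6 rose (13 and 7 adjusted over the list alone; camera adjusted p = 0.410), with the glycolytic regulator PFKFB3 at -0.73 (SE 0.09) and its relative PFKFB4 at 0.54 (SE 0.09). The PFKFB3 transcript carried 2 copies of CTACCAG and that of PFKFB4 none. None of the 13 mitochondrially encoded transcripts passed the edgeR test or did so adjusted over the list alone (camera adjusted p = 0.260); 1 was higher at an unadjusted p under 0.05, DESeq2 called 1 higher, and limma called 0. Without siSCR replicate 1 or siBARD1 replicate 4, 1 rose, and 2 without siSCR replicate 4. MT-ATP8, with the smallest p of these transcripts, had 0.35 (SE 0.16, adjusted p = 0.101), but 22.2% of its exonic bases are shared with MT-ATP6.

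Of 29 mesenchymal and matrix genes, 12 fell and 4 rose (12 and 6 adjusted over the list alone; camera adjusted p = 0.0846). LOX, an enzyme that crosslinks collagen, stood at 0.74 ± 0.11 and 1.39 ± 0.27 CPM (SD, n = 4 each; 0.90, SE 0.26, adjusted p = 0.0103), and its transcript lacked CTACCAG. The mesenchymal list passed with DESeq2 statistics (0.0443), with no low-count filter (0.0352) and in the fry test (0.00072), but its camera adjusted p was 0.508 with an estimated correlation. Without siSCR replicate 1, 7 of its genes rose. Of 26 epithelial junction and keratin genes, 9 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.410), and its median (0.02) and mean (-0.06) differed in sign. The median was 0.14 with 7 genes higher without siSCR replicate 1, -0.08 without siSCR replicate 3, -0.03 without siBARD1 replicate 1 and -0.0049 without siBARD1 replicate 5. Mean levels of this list were 0.25 in siSCR replicate 1 and -0.11 to -0.05 in the other siSCR libraries on the log2 scale. OCLN, a tight junction protein, fell from 71.4 ± 3.10 to 38.2 ± 1.68 CPM (-0.90, SE 0.06; CTACCAG in the 3′ UTR) and the keratin gene KRT18 had -0.87 (SE 0.15). Of 14 BCL2 family genes, 6 fell and 3 rose (6 and 3 adjusted over the list alone; camera adjusted p = 0.410), with a median of 0.07 and a mean of -0.02. BMF, which promotes apoptosis, stood at 1.02 ± 0.40 and 3.49 ± 0.65 CPM (1.74, SE 0.24) with CTACCAG once in its 3′ UTR, and the survival gene BCL2A1 at 7.27 ± 0.72 and 3.24 ± 0.60 CPM (-1.15, SE 0.15).

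Most markers of other cell types were barely detected. Under 1 CPM in every library were 12 of 14 leukocyte markers, all 11 endothelial and erythroid markers, 7 of 9 fibroblast markers and all 13 markers of acinar and endocrine pancreas. The fibroblast markers above that level were THY1, at means of 8.54 and 7.51 CPM in siSCR and siBARD1, and PDGFRB, at 1.24 and 1.21 CPM. The leukocyte markers above it were CD14 and CD8A, at most 1.26 and 1.22 CPM. These 4 were named after their values were seen. Over all marker lists, 2 leukocyte and 2 fibroblast markers were tested by edgeR, and 0 changed, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma.

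Fold changes moved with gene length. In the shortest of 5 equal groups of tested genes, with a median length of 1488 bp, 524 genes fell and 239 rose (median log2 fold change -0.06). In the longest, with a median length of 10125 bp, 522 fell and 951 rose (median 0.08). Protein-coding genes made up 12751 of the genes tested, with 2688 higher and 2854 lower. Processed pseudogenes, whose reads can be shared with their parent genes, numbered 411, with 21 higher and 40 lower.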

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

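The tests of the sequence anywhere in the transcript, of lists among transcripts without CTACCAG, of single lists over splits of the libraries and of list levels per library were chosen after the results they bear on were seen.

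A library far from the other 3 of its group appeared for 11 of 210 sets of 4 values looked at, close to the 10.5 that chance gives at 1 in 20. The measure is the gap to the nearest library divided by the range. In siBARD1 the highest value was replicate 1 for CPEB3 (0.868), STARD4 (0.869) and ABCC1 (0.874), replicate 3 for ALDOC (0.830) and replicate 4 for TJP1 (0.932), and the lowest was replicate 1 for SLC3A2 (0.962). In siSCR, replicate 1 was lowest for PM20D2 (0.898) and XRCC2 (0.849) and highest for LGALS3BP (0.887) and STARD4 (0.840), and replicate 5 was lowest for BBC3 (0.934).

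The 35 ways to split the 8 libraries into 4 and 4 bear on chance. Only 1, the real one, gave as many changed genes, 5946 against a highest of 0 in the others, as tested by edgeR alone. Only 1 gave as many genes changed at least 2-fold, 320 against 0. At an unadjusted p under 0.05 in edgeR there were 7228 genes, and at most 2605 in the others. The real grouping thus stood out for both counts, but 1 of 35 is the smallest share that this test can give. The other splits mix the groups, which widens the spread within each side. The splits also cannot tell the siRNA from another difference between the groups. Chance cannot be excluded for the number of lists called by camera at the preset correlation. There, 18 splits gave as many as the real 6, with a highest of 9 in the others. Per list, splits with a camera p as small numbered 16 for homologous recombination (smallest other p 1.10e-06, real 0.00976), 21 for G2/M (2.29e-10, real 0.00582), 5 for immediate early genes (4.15e-05, real 0.00445), 3 for G1/S (1.04e-20, real 2.08e-16) and 2 for NF-kB (9.42e-05, real 1.00e-04). Chance cannot be excluded for any of these 5 by that measure. For small RNA silencing genes only 1 split, the real one, gave so small a camera p (3.57e-04, next 0.00117). This count was 1 of 6 made after the results were seen. With the list's camera adjusted p of 0.508 at an estimated correlation, it does not exclude chance firmly, although the list passed in fry (adjusted p = 7.2e-04). The 2 splits with a smaller p for G1/S both put siSCR replicate 1 with 3 siBARD1 libraries against the other 3 siSCR libraries and 1 siBARD1 library, so they keep much of the real contrast. The same holds for the other split for NF-kB, which put siSCR replicates 1, 3 and 5 with siBARD1 replicate 3. It also holds for most, but not all, of the other splits for immediate early genes.

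The first pattern weighed is the genes that fell at least 2-fold, of which CSTB and FBXO7 fell further than BARD1 itself. Length and GC content gave these genes a fitted median log2 fold change of only -8.96e-04, which argues against length bias. Of the 179, 0 overlapped another such gene on the same strand, which argues against reads shared among these genes on 1 strand. Reads shared with opposite-strand genes, or with genes that did not fall, were not tested. The 7-base sequence CTACCAG was found on part of the genes as the most depleted of 16384, of which rare ones could not be found. In the other genes it again ranked 1 and shifted log2 fold changes by -0.19 against -0.07 to 0.05 in 1000 shuffles. There it had an odds ratio of 10.3 (95% interval 6.18 to 17.1) in the 3′ UTRs of genes that fell at least 2-fold. Also in these other genes, it was carried anywhere in the transcript by 57 of 76 that fell at least 2-fold (75%) and 23.6% of the rest (odds ratio 11.1, interval 6.47 to 19.1), which argues against loss of BARD1 protein as the whole cause of these falls. A candidate explanation is therefore direct off-target repression by a BARD1 siRNA strand whose seed pairs with CTACCAG. BARD1 itself carries the sequence in 2 copies, and the siRNA sequence is not given in the sources used here. Most genes with a copy in the 3′ UTR did not fall at least 2-fold, so a copy alone was not enough for such a fall. Of the 179 fallen genes, 30 carried no copy and 35 had no searched transcript, and effects of BARD1 loss stay open for these. Such effects also stay open for any single gene with a copy, because 23.6% of genes that did not fall at least 2-fold carried one.

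The second pattern is the fall of G1/S and DNA replication genes. Their median log2 fold change was -0.46 (quartiles -0.55 and -0.38) in the 42 of 47 members without any of the 3 most depleted 7-base sequences in the 3′ UTR, which argues against direct seed matches there as the cause. The camera call also held among transcripts without CTACCAG (adjusted p = 8.26e-16), but at the preset correlation; over all genes the list was not called with an estimated one (0.508). The median was -0.47 after a fit on length and GC content, and at most -0.42 without any 1 of the 8 libraries, which argues against a length bias and a single odd library. Open explanations are loss of BARD1, a slower cell cycle, and indirect effects of off-target repression, for example of TIMELESS or TOPBP1, which may act on replication; one siRNA cannot separate these, and the count of 3 of 35 splits leaves chance open for the list test, although levels of the list did not overlap between groups.

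The third pattern is that longer genes rose and shorter genes fell. A difference in library size is argued against by thinning every library to 17816547 counts, which left 1.03 times the slope on gene length. The slope per doubling was 0.036 (SE 0.003) on coding length and 0.013 (SE 0.002) on 3′ UTR length, a difference of -0.023 (SE 0.004). This met the prediction set beforehand for a length bias of whole transcripts between libraries, a coding slope at least as large. Such a bias need not favour coding length, and the 3′ UTR length was that of the longest annotated form, so the comparison cannot decide. RNA integrity or fragmentation could contribute, and no biological cause of a dependence on coding length was tested. For the release of control siRNA or microRNA sites in 3′ UTRs, the most enriched 7-base sequence shifted the genes not used to find it by 0.013, within the shuffles (-0.04 to 0.04); this speaks against 1 dominant site but not against many weak ones, so the explanation stays open.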

How the results depend on the processing

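The alternative over transcripts without CTACCAG was chosen after seeing the data; all others were planned. BARD1 stayed lower and past the threshold in every alternative, from -2.76 to -2.62 on the log2 scale without single libraries. With single libraries left out, the count of changed genes ranged from 5124 (without siBARD1 replicate 4) to 6344 (without siSCR replicate 1). It was 5820 in DESeq2, of which 5735 were shared with the main 5946, 5916 in limma-voom and 4103 at an adjusted p under 0.01. No named gene or list called in the main test changed direction; some lists not called did, and without single libraries the medians of the interferon, epithelial and end joining lists changed sign. The balance of all changed genes also turned: 3616 genes were higher and 2478 lower with total count scaling, and 3482 and 2588 with the upper quartile.

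Genes changed at least 2-fold numbered 84 with log2(FPKM + 1), 200 with log2(FPKM + 0.1), where the pseudocount shrinks low genes, and 280 against a fold of 1.2. Over the smaller set of transcripts without CTACCAG, 3909 genes changed, 1784 of them lower, and 111 at least 2-fold. Camera adjusted p-values for homologous recombination and G2/M were 0.0531 and 0.0531 with total count scaling, 0.0622 and 0.0508 with a minimum of 1 CPM, and 0.0698 and 0.0583 for protein-coding genes. Without CTACCAG transcripts they were 0.0682 for G2/M, 0.107 for immediate early genes and 0.115 for small RNA silencing. With single libraries left out, homologous recombination ranged from 0.0116 to 0.103, losing its call without siSCR replicates 4 and 5 and siBARD1 replicate 1, and G2/M from 0.0027 to 0.160, losing it without siSCR replicate 5 and siBARD1 replicate 1. With an estimated correlation no list passed: 0.508 for G1/S, 0.837 for homologous recombination and for G2/M, 0.498 for NF-kB, 0.747 for immediate early genes and 0.508 for small RNA silencing. In fry, G2/M gave 0.0833, and the other lists called by camera passed: G1/S 0.00175, homologous recombination 0.0166, NF-kB 5.42e-04, immediate early genes 0.00211 and small RNA silencing 7.2e-04. Lists without a camera call also passed in fry: end joining 0.0341, checkpoint signalling 0.0341, PARP and base excision repair 0.0166, BCL2 family 0.0166 and mesenchymal genes 7.2e-04. Mitochondrially encoded transcripts passed only with limma-voom (0.0285). Apart from smaller gene sets and pseudocounts, the causes were not tested.

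With the replicate number as a replicate block, 6604 genes changed, 5896 of them shared with the fit without it, and no list call was lost. Whether the numbers pair the libraries was not settled. Same-number correlations of deviations were 0.139, 0.129, 0.034 and -0.032 for replicates 1, 3, 4 and 5. Other pairs ran from -0.28 to 0.14, and 3 of the 8 libraries correlated best with their own number.

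Among single named genes, TRAF1, FN1, ABRAXAS1, MT1X, CLDN3, SHLD1, SRXN1, KLF6 and SAMD9 lost their call in some alternatives, and MT-ATP8 gained one. In simulation, with few genes changed, 66% of genes changed 1.5-fold and 36% at the smallest simulated fold were recovered. These shares do not give the sensitivity in the data, and depth was not separated from the spread between libraries.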

Other observations

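The test of microRNA families was chosen after the results it bears on were seen.

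Members of the silencing machinery list other than TNRC6A and AGO4 also rose. TNRC6B had a log2 fold change of 0.65, DICER1 0.52, AGO2 0.45, AGO3 0.43 and TARBP2 0.31, each past the edgeR threshold. These 5 were chosen after their values were seen. The list's mean level lay higher in all 4 siBARD1 libraries than in all 4 siSCR libraries, by 0.29 on the log2 scale (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0898 over 22 lists). Levels of 7 of the 22 lists separated the groups without overlap, each with the same exact permutation p. Besides small RNA silencing, which was higher, the lower ones were G1/S, homologous recombination, Fanconi anaemia, PARP and base excision repair, NF-kB and immediate early genes. This measure was chosen after seeing the data.

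Transcripts with sites of abundant microRNA families were slightly higher in siBARD1. For 21 families, 16 had genes with a 7-base site in the 3′ UTR shifted upward, and the median shift was 0.025 on the log2 scale, above that of 100% of 10000 sets of 21 other 7-base sequences of like GC content and frequency. The highest of these shifts were those of the miR-25/92 site (0.055) and the miR-21 site (0.048). All searched genes were used here. The most enriched sequence of the earlier search, AATGTGA, is the miR-23 site, and it shifted the genes not used to find it by only 0.013. Some sequences that are not sites of these families shifted by similar amounts, such as TATATAA (0.043). A hypothesis is that targets of endogenous microRNAs may have been slightly released in siBARD1; what would release them was not tested, and small RNA was not measured here.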
